A study of Homo sapiens with 3 samples.

How the data were processed

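Gene expression was measured in single cells of blood vessel organoids at day 45 of culture. The organoids were grown from H1, an established human embryonic stem cell line, which carried a doxycycline-inducible NEUROD1-P2A-GFP cassette inserted with a PiggyBac transposon. There were 3 libraries and 1 library per group: no induction, 15 days of induction and 45 days of induction. Per the labels, doxycycline was given at 1 µg/ml, and BDNF and NT-3, factors that sustain neurons, were in the medium of every organoid from day 15. The labels do not say which 15 days were induced. For each library 5 to 6 organoids were pooled and dissociated with papain at 20 U/ml for 30 min, the suspension was passed through a 40 µm filter, and cells were captured on a Chromium Chip B and prepared with the Chromium Single Cell 3′ v3 kit, which reads the 3′ end of polyadenylated transcripts.

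The deposited values are counts of unique molecular identifiers (UMIs) per gene and barcode, with no normalization; every value was a whole number. Per the submitters' processing notes the counts came from Cell Ranger 3.0.0 on genome build GRCh38, and the headers of the matrices name software version 3.0.1. The gene annotation used for counting was not given in the sources used here. Of the 33538 gene identifiers in the files, 33456 were found by Ensembl identifier in GENCODE 29, from which the coordinates were taken (GRCh38, 1-based). The identifiers hold no entry for GFP or for the cassette, so NEUROD1 itself was the only readout of the transgene. The 3′ end of a cassette transcript can lie outside the annotated NEUROD1 gene, so a low NEUROD1 count does not contradict a label. In this capture, UMIs limit the effect of amplification, but RNA released from broken cells enters other droplets and is counted there.

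The files held 10232 barcodes and 59879923 UMIs without induction, 5962 barcodes and 49488425 UMIs for 15 days, and 10765 barcodes and 64171327 UMIs for 45 days. Barcodes with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs were kept, which left 86.6%, 89.0% and 89.6%. Doublets were then removed within each library, as the cells with the highest share of simulated doublets among their neighbours, at 0.8% of cells per 1000 barcodes. This took out 7.09%, 4.24% and 7.71% of cells. A test placed 150 doublets, made by adding pairs of cells, among 3000 cells of the uninduced library. Of these doublets, 55.3% were among the 300 cells that it removed, so some doublets remain. The test took out a larger part of the cells than the 7.09% removed from that library. It therefore does not give the share of doublets removed from the libraries. The 8230, 5078 and 8900 cells that were left were clustered together without integration: totals were normalized to 10000, log-transformed values of 2000 variable genes gave 30 principal components, and Leiden clustering at resolution 1.0 on 15 nearest neighbours gave 28 clusters.

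Clusters were named "X-like" from 14 marker sets. A marker counted when it was at least 2-fold above the other cells and had a UMI in at least 10% of the cluster's cells. A class name needed 3 such markers and 1 in 3 of the markers measured. Clusters left over were compared with the named clusters that were neither mesenchymal, mural nor cycling, and were called mesenchymal-like on 3 markers. A cluster with 3 liver secretory genes among its top 20 genes stayed unnamed. This scoring was set after the data were seen, as were the requirement of 1 in 3 and the liver rule. It left out cluster 21, which held 0.061% of cells without induction, 3.86% at 15 days and 0.011% at 45 days. Cluster 26 met 9 of 10 epithelial markers, but its top 10 genes held 0 of them and 1 marker of another class. It is therefore given by number without a class name, and the epithelial-like clusters 10 and 18 were compared by number.

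With 1 library per group no test between groups is possible, so no p-value or standard error is given. UMIs were summed over the cells of a library or class and divided by the total and scaled to a common total (CPM). Ratios are log2 of CPM with 5 CPM added to each side; folds printed beside CPM are plain ratios without that addition. Sums carry exact Poisson 95% intervals, shares above 0 exact Clopper-Pearson 95% intervals, and folds exact conditional binomial 95% intervals; a share of 0 is given with the limit of 3 cells of the total. All of them cover counting error only, and not the difference between organoids or captures. Those of sums and folds also leave out the difference between cells, since many UMIs can come from 1 cell. A sum of 0 was set to 3 UMIs, which in the kept cells is 0.0585, 0.0661 and 0.0541 CPM for none, 15 and 45 days. Genes at 50 CPM or more in at least 1 of the 2 libraries entered the counts of genes at least 4-fold apart. These counts take the ratio with 5 CPM added, so a gene with a plain fold somewhat above 4 may not be in them, and they describe size and are not calls. Shares of cells with a UMI were compared after thinning each cell to 2000 UMIs, which left out 331, 265 and 464 shallower cells.

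The genes named were the 10 highest and 10 lowest log2 ratios over all cells and the 5 highest and 5 lowest within a class, leaving out mitochondrially encoded, ribosomal protein, clone-based and LINC genes. From each gene list described, up to 3 members with the highest mean CPM and the members with the highest and lowest ratio were named, and NEUROD1 always. Some genes that these rules name are not reported here. Named outside these rules, after their values were seen, were the leading genes of clusters, further members of the transmitter and subtype lists in neuron-like cells, neuronal genes set beside NEUROD1 in other cells, and some genes repeated in another class. The 47 gene lists held 525 genes, of which 524 were matched, 2 of them by an older symbol (CYR61 and CTGF). RGS5 is carried by 2 identifiers, and the values given are those of ENSG00000143248. A member counted as measured at 5 CPM in at least 1 of the libraries, and a list needed 5 measured members. A list's median log2 ratio was placed among the medians of 10000 random lists of the same size, matched in 20 bins of expression; this percentile describes these libraries. Medians were computed for every list over all cells and in every class, and the class and comparison in which each list is described were chosen after these medians had been computed. A percentile near 0 or 100 therefore stands among many that were looked at, with no correction for their number. The lists for neural progenitors, glia and neural crest, skeletal muscle, cardiomyocytes, pluripotent cells, GABAergic and catecholaminergic neurons had fewer than 5 measured members in every comparison reported here, so no median is given for them. The groups, the lists, the marker sets, the filters, the designs and the rule for named genes were fixed before the data were examined.

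The computation of ratios and lists was tested on simulated data. With counts drawn at the real means for 45 days against no induction, over 2644 genes, 100% of genes set 8-fold higher or lower passed the 4-fold threshold and 0.0% of unchanged genes did; 15 days against none (2717 genes) and 45 against 15 days (2877 genes) gave the same shares. A list of 12 genes set 2-fold higher reached percentile 100 in each. The draws were Poisson counts of whole libraries, with no variation between cells, organoids or captures. They check the computation only, and not the values of classes with few cells. Alternatives fixed in advance were no cell filter, a mitochondrial limit of 10%, no doublet removal, Leiden resolutions of 0.5 and 2.0, list genes and markers left out of the variable genes, each library clustered alone, cells thinned before clustering, median-of-ratios scaling, pseudocounts of 1 and 10 CPM, floors of 20 and 100 CPM, list members at 20 CPM, the mean of each cell's own CPM, and other depths of thinning. Chosen after seeing the data were a count of neuron-like cells from markers alone, naming on 3 markers with each library clustered alone, and sums without neuron-like cells, without the liver-gene cluster, without the collagen-led cluster 15 and without the hypoxia-led cluster 6. Tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9.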

Results

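Organoids of 1 stem cell line were compared after 0, 15 and 45 days of NEUROD1 induction, all harvested at day 45, with 1 library per group. NEUROD1 is a transcription factor that drives neuronal differentiation, and blood vessel organoids are self-organising cultures of endothelial and mural cells within a mesenchymal bed. The design asks what cells NEUROD1 adds to such an organoid and what the vascular cells look like beside them. The median barcode had 4903, 6961.5 and 5408 UMIs without induction, at 15 days and at 45 days. After filtering, 8230, 5078 and 8900 cells remained, with medians of 5152, 7321.5 and 5570.5 UMIs and 4.60%, 3.79% and 2.96% mitochondrial UMIs.

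NEUROD1 (ENSG00000162992) was high in the 45 day library and low in the library labelled 15 days. It was counted 77 times in the uninduced library, 67 times at 15 days and 2386 times at 45 days, which is 1.502 CPM (1.19 to 1.88), 1.48 CPM (1.14 to 1.88) and 43.0 CPM (41.3 to 44.8). Of the 77 uninduced UMIs, 74 came from 1 cell of cluster 26, while 61 of the 67 at 15 days came from neuron-like cells. Among neuron-like cells NEUROD1 stood at 739 CPM (709 to 770) at 45 days and 11.6 CPM (8.85 to 14.9) at 15 days, a fold of 63.9 (49.6 to 83.8). Thinned to 2000 UMIs, 65.9% of neuron-like cells (59.5 to 72.0) had a NEUROD1 UMI at 45 days and 4.26% (2.06 to 7.69) at 15 days, against 73.5% and 9.37% unthinned. In endothelial-like cells of the same libraries the thinned share was 0 of 190 and 0 of 300 cells. Median depths were 5267 and 9473 UMIs in neuron-like cells and 6134.5 and 8330.5 in endothelial-like cells at 45 and 15 days. The neuron-like cells formed clusters 19 and 20, with medians of 3397 and 1965 UMIs in cluster 19 and 21278 and 25510.5 in cluster 20. Thinning left out 62 of 189 cells of cluster 19 at 45 days and 64 of 123 at 15 days, and none of cluster 20. Thinned shares of neuron-like cells, here and below, therefore weigh cluster 20 more than the class does.

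The NEUROD1 transcript lies on chromosome 2 at 181676467 to 181680876 (GRCh38, minus strand) and has 2 exons of 447 and 2405 bp. The larger holds the whole coding sequence, 181677793 to 181678860, and a 3′ untranslated stretch of 1326 bp that includes the stop codon. Reads of the 3′ kit fall near the end of a transcript, and the cassette's own end may lie outside this gene. Outside neuron-like cells and cluster 26, NEUROD1 was at 0.0592 CPM without induction, 0.101 CPM at 15 days and 2.53 CPM (2.12 to 3.00) at 45 days. The last is 0.342% (0.285 to 0.408) of the neuron-like level, beside 0.290% to 0.559% for 8 other neuronal genes in that library, with SCG3 lowest, SLC17A6 at 0.360%, PRPH at 0.471% and NEFL highest. NEUROD1 was among the leading genes of neuron-like cluster 19. With markers and list genes left out of clustering, 302 and 295 neuron-like cells gave 11.6 CPM at 15 days and 737 CPM at 45 days. The labels do not say which 15 days were induced, so differences of that library are described by its label.

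**Figure D1:**
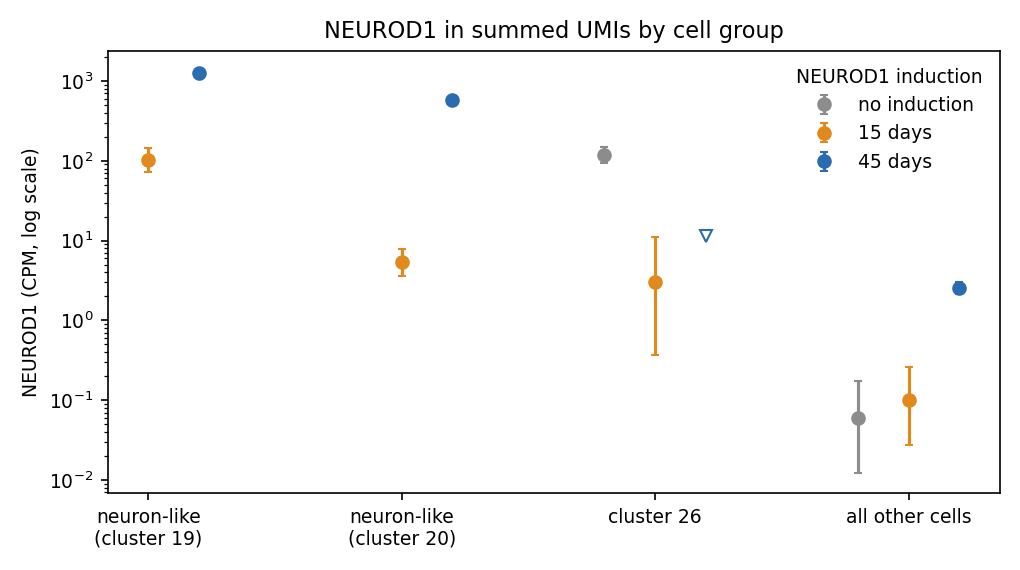
NEUROD1 in summed UMIs (CPM, log axis) for the neuron-like clusters 19 and 20, cluster 26 and all other cells, by library, with exact Poisson 95% intervals; the open triangle is the level of 3 UMIs where none was counted. The neuron-like clusters stand at 1253 and 585 CPM at 45 days and at 103 and 5.46 CPM at 15 days.

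Neuron-like cells were found in both induced libraries and in none of the 8230 uninduced cells, which allows a share of up to 0.0365%. They made up 5.89% of cells (5.26 to 6.57, 299 cells) in the library labelled 15 days and 3.30% (2.94 to 3.70, 294 cells) at 45 days. Endothelial-like cells, whose largest cluster was led by genes that include PECAM1 and CDH5, made up 6.16% (5.65 to 6.70) without induction, 6.42% (5.76 to 7.13) at 15 days and 2.47% (2.16 to 2.82) at 45 days. The 45 day share was 0.401 times the uninduced share (0.341 to 0.471). The 15 day share was 1.04 times it (0.904 to 1.20). Without the cell filter the neuron-like shares were 3.40% and 1.12%. Counted as cells with 5 of 15 neuron markers after thinning, they were 2 of 7899 cells without induction (0.0253%, 0.0031 to 0.0914), 4.88% at 15 days and 2.26% at 45 days. Naming with each library clustered alone on 3 markers called 5.35% of uninduced cells neuron-like, from a cluster led by GABRA2 and APCDD1 that had 3 of 15 neuron markers.

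Mesenchymal-like cells were the majority everywhere, at 69.9% (68.9 to 70.9) without induction, 54.0% (52.6 to 55.4) at 15 days and 69.1% (68.2 to 70.1) at 45 days. Over 8 alternatives this share ran from 70.4% to 76.7% without induction, 55.0% to 65.6% at 15 days and 68.7% to 76.0% at 45 days. The values above for no induction and 15 days lie under all 8. Mural-like cells, the pericytes and smooth muscle that wrap vessels, made up 7.98% (7.41 to 8.59), 15.9% (14.9 to 16.9) and 11.6% (10.9 to 12.2). Their share depended on the setting, from 3.04% to 8.07% without induction and from 4.91% to 11.6% at 45 days. At 15 days it ran from 5.82% to 14.9%, and the value above exceeds all 8 alternatives. The uninduced library had the lowest mural-like share in each of the 8. Cycling cells made up 8.48% (7.89 to 9.10), 6.54% (5.87 to 7.25) and 6.76% (6.25 to 7.31). Haematopoietic-like cells, led by C1QA and TYROBP, made up 0.875% (0.685 to 1.10), 1.65% (1.32 to 2.04) and 0.832% (0.653 to 1.04). Epithelial-like cluster 10, led by KRT15, KRT5 and TP63, held 2.47% (2.14 to 2.83), 4.18% (3.64 to 4.76) and 4.89% (4.45 to 5.36). The epithelial-like cluster 18, led by GABRP and SPRR3, held 3.17% (2.80 to 3.57), 0.551% (0.367 to 0.796) and 0.831% (0.653 to 1.04). Cluster 26, led by GNRH2, SPINK1 and MLN and given no class name, held 0.923%, 1.04% and 0.191%.

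**Figure D2:**
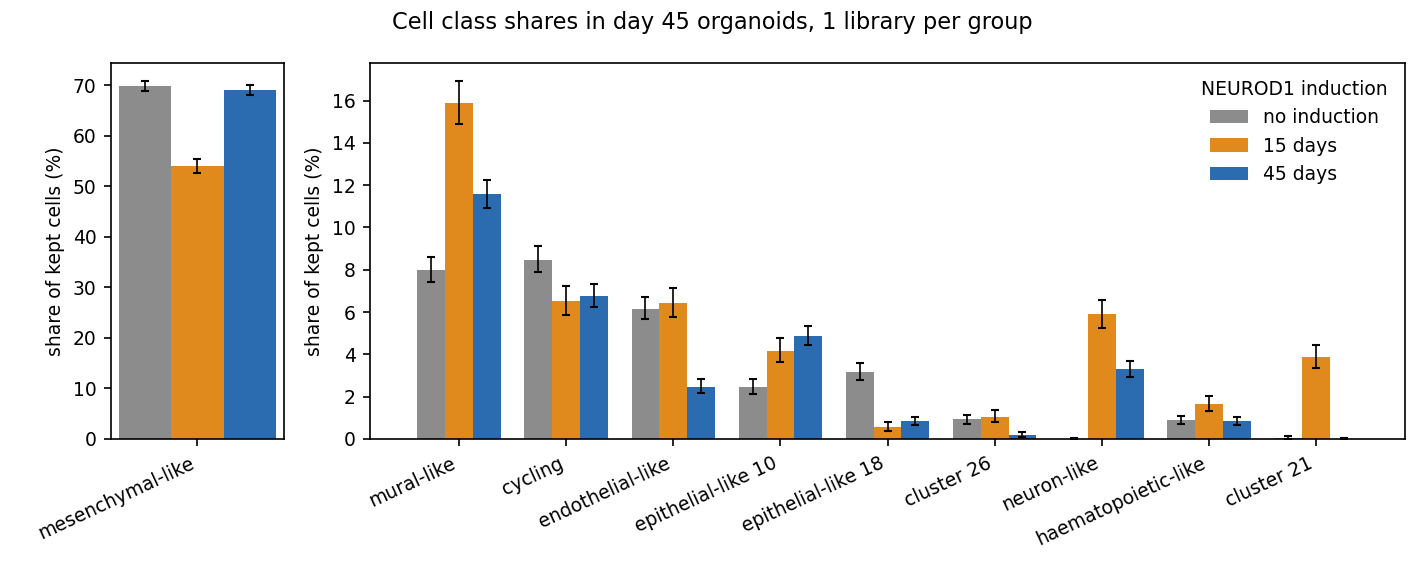
Share of kept cells (%) in each class, and in clusters 10, 18, 21 and 26, for the library without induction and those labelled 15 and 45 days, with exact 95% binomial intervals; mesenchymal-like cells have their own axis. Neuron-like cells appear at 5.89% and 3.30% in the induced libraries, and endothelial-like cells stand at 2.47% at 45 days against 6.16% and 6.42%.

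Against no induction, the 45 day organoids had more RNA of neuronal genes and less of endothelial and collagen genes. Of 2922 genes, 14 were at least 4-fold higher and 12 at least 4-fold lower, with 5 CPM added to each side here and in every count of such genes. The neuronal cytoskeleton genes NEFL (330 against 10.4 CPM, 31.8-fold, 29.2 to 34.8), PRPH (114 against 1.70 CPM, 67.2-fold, 54.4 to 84.0) and NEFM (478 against 82.2 CPM, 5.81-fold, 5.63 to 6.01) were higher. So were RTN1 (96.6 against 0.858 CPM), STMN4 (54.0 against 0.117 CPM), NRN1 (63.3 against 4.04 CPM), DCX (64.1 against 5.19 CPM), GAP43 (94.0 against 12.8 CPM) and KIF5C (92.1 against 13.9 CPM). LHX9, a homeobox gene of limb mesenchyme and some neurons, was at 92.6 against 10.3 CPM (8.97-fold, 8.20 to 9.83). The lowest genes included 4 whose products liver cells secrete: AFP at 1.62 against 127 CPM (78.1-fold, 63.4 to 97.2), APOA2 at 2.65 against 82.9 CPM, APOA1 at 4.02 against 95.5 CPM and TTR at 0.216 against 52.1 CPM. Of the 6496 uninduced AFP UMIs, 3608 came from 5 cells of cluster 21 and 1603 from 76 cells of cluster 26, while 1707 of the 2669 TTR UMIs came from cells outside both (33.8 CPM there, against 0.109 CPM at 45 days). Also lower were COL15A1 (6.98 against 92.5 CPM, 13.26-fold, 11.95 to 14.74), the collagen-binding proteoglycan DCN (118 against 566 CPM, 4.795-fold, 4.668 to 4.926), the WNT antagonist DKK2 (10.1 against 63.2 CPM), GABRP (13.5 against 110 CPM) and GNRH2 (10.4 against 66.8 CPM). Left without neuron-like cells, the count of genes at least 4-fold apart was 16 in place of 26.

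By list, 13 of 14 measured neuron genes were at least 2-fold higher at 45 days and none lower, with a median log2 ratio of 1.99 (percentile 100), led by NEFL at 4.45 and with STMN2 at 1.66 and SCG2 at 0.70. Without neuron-like cells that median was 0.70. Synapse genes had a median of 0.78 (percentile 100, 4 of 12 at least 2-fold higher), with SYP at 2.02, RAB3A at 1.88 and VAMP2 at 0.69. Excitability genes stood at 0.58 (99.95, 2 of 7) and glutamatergic genes at 0.54 (99.6, 1 of 5), with SLC17A6 at 1.75. The endothelial list had a median of −0.89 (percentile 0.0), with 5 of 15 genes at least 2-fold lower, TEK at −1.71 and PECAM1 at −0.96, while EMCN was at 0.40. Epithelial genes stood at −0.71 (0.0, 3 of 9 lower, KRT18 at −1.47 and KRT8 at −1.22) and the mesenchymal markers at −0.96 (0.0, 6 of 12 lower). The list of fibrillar collagen and matrix genes was at −0.59 (0.0, 5 of 14 lower and 1 higher), where COL1A1 was at −1.94 and ELN at 1.30. Hypoxia and glycolysis genes were at 0.75 (100, 2 of 17 higher, ENO1 at 0.79 and ANKRD37 at 1.13). The mural list (0.16, percentile 71.7), the cycling list (−0.08, 2.85), the haematopoietic list (0.10, 31.3) and the chondrogenic list (0.33, 95.6) lay within the central range of random lists. Scaling by median of ratios shifted all genes by −0.09 here, by −0.16 at 15 days and by 0.05 at 45 against 15 days. Within classes the shifts at 45 and 15 days were −0.04 and −0.08 (endothelial-like), −0.12 and −0.13 (mural-like) and −0.11 and −0.15 (mesenchymal-like). In neuron-like cells, at 45 against 15 days, the shift was −0.006. List medians below are to be read against the shift of their own class and comparison.

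In the library labelled 15 days, neuronal RNA was again higher than without induction and collagen RNA was lower. Of 3096 genes, 48 were at least 4-fold higher and 13 lower; without neuron-like cells the total was 29 in place of 61. NEFL was at 826 against 10.4 CPM (79.6-fold, 73.0 to 86.8), NEFM at 1307 against 82.2 CPM (15.9-fold, 15.4 to 16.4) and PRPH at 349 against 1.70 CPM (206-fold, 167 to 257). RTN1 (254 against 0.858 CPM), NRN1 (213 against 4.04 CPM), STMN4 (104 against 0.117 CPM), OLFM1 (91.2 against 1.09 CPM) and INA (71.1 against 0.0975 CPM) followed. ALB, the main plasma protein of liver, was at 411 against 0.371 CPM (1109-fold, 710 to 1842) and CST1 at 138 against 0.273 CPM; both lead cluster 21, which held 3.86% of this library. Lower were COL15A1 (5.42 against 92.5 CPM, 17.1-fold, 15.0 to 19.5), DKK2 (3.73 against 63.2 CPM, 17.0-fold, 14.5 to 19.9), GABRP (8.57 against 110 CPM), DCN (66.1 against 566 CPM, 8.56-fold, 8.24 to 8.89), PTX3 (10.1 against 74.8 CPM), SFRP2 (17.1 against 105 CPM), CXCL14 (133 against 784 CPM), PITX1 (45.8 against 236 CPM), LUM (208 against 1064 CPM) and COL1A1 (324 against 1649 CPM, 5.09-fold, 5.00 to 5.18).

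All 14 measured neuron genes were at least 2-fold higher at 15 days (median log2 ratio 2.80, percentile 100), with NEFL at 5.75, NEFM at 3.91 and SCG2 at 1.09. The median was 0.88 without neuron-like cells. Synapse genes had a median of 0.98 (100, 6 of 12 higher, RAB3A at 2.66), excitability genes of 1.03 (100, 5 of 10, SCN9A at 2.18) and glutamatergic genes of 1.00 (99.94, 3 of 5, SLC17A6 at 2.54, with GRIA2 at −0.75). The endothelial list was at 0.01 (percentile 1.42, none of 15 at least 2-fold apart), and its sign depended on the setting. Mesenchymal markers were at −1.58 (0.0, 7 of 12 lower, DCN at −3.005 and COL1A2 at −2.00), fibrillar collagen and matrix at −0.73 (0.0, 5 of 14 lower, COL1A1 at −2.33). Cycling genes stood at −0.35 (0.0, none of 10 at least 2-fold apart, CDK1 at −0.58) and hypoxia and glycolysis at 0.86 (100, 4 of 16 higher, HK2 at 1.252). Haematopoietic genes stood at 0.67 (99.3, 1 of 7 higher, C1QA at 1.26), mural genes at 0.28 (91.5) with TAGLN at −2.23 and MCAM at 0.93. The chondrogenic (−0.14, percentile 0.86) and epithelial (−0.15, 0.515) medians changed sign under an alternative.

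Set side by side, the induced libraries differed in the endothelial and neuron lists and in single genes that include TTR, ALB and AFP. Of 3092 genes, 1 was at least 4-fold higher at 45 days than in the library labelled 15 days, LHX9 (92.6 against 15.3 CPM, 6.07-fold, 5.61 to 6.58), and 17 were lower. With cluster 21 left out the total was 3 in place of 18. NEUROD1, at 43.0 against 1.48 CPM, lay under the floor of 50 CPM and did not enter these counts. The 10 lowest were TTR (0.216 against 440 CPM, 2031-fold, 1162 to 3931), ALB (0.180 against 411 CPM, 2279-fold, 1239 to 4753), AFP (1.62 against 841 CPM, 518-fold, 421 to 644), APOA1, APOA2, APOC3, SERPINA1, AHSG and AMBP, and CST1 at 0 against 138 CPM, at least 2551-fold lower. Higher at 45 days, after LHX9, were the transcription factors TWIST1 (320 against 108 CPM, 2.97-fold), PITX1 (136 against 45.8 CPM), PRRX2 (105 against 36.8 CPM), PRRX1 (279 against 126 CPM), ZFHX4 (103 against 39.6 CPM), BCL11A (121 against 50.7 CPM) and HOXA13 (94.5 against 42.5 CPM), and ASPN (61.2 against 19.6 CPM) and CXCL14 (289 against 133 CPM). The neuron list had a median of −0.90 (0.0, 5 of 14 lower), −0.22 without neuron-like cells, and the endothelial list of −0.97 (0.0, 5 of 14 lower), with KDR at −1.35 and PECAM1 at −1.16. Proneural factors stood at 0.32 (100), with NEUROD1 at 2.89 and EBF1 at −0.07. Sensory neuron genes were at −0.60 (0.07), with PRPH at −1.57. Fibrillar collagen and matrix genes stood at 0.21 (100, none of 14 at least 2-fold apart) and hypoxia and glycolysis at −0.06 (44.4).

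Within neuron-like cells, 45 and 15 days differed in NEUROD1, in proneural factors and in interferon and neuroendocrine genes, and the neuron list had a median near 0. Cluster 20, led by NEFL, PRPH and RTN1, held 176 of the 299 cells at 15 days. Cluster 19, led by NEUROD1, INSM1, NHLH1 and HES6, held 189 of the 294 at 45 days. By summed UMIs, cluster 20 held 4944202 of 5273351 at 15 days and 2345162 of 3049068 at 45 days. The values therefore mix these clusters in different parts, with most UMIs from cluster 20 in both libraries. Cells with under 1% mitochondrial UMIs made up 40.48% at 45 days and 17.06% at 15 days, or 61.38% and 32.52% in cluster 19 and 2.86% and 6.25% in cluster 20. Of 3786 genes, 17 were at least 4-fold higher at 45 days and 9 lower. After NEUROD1, the highest were MMP9 (53.8 against 0.759 CPM, 70.9-fold, 27.2 to 263) and TNC (53.1 against 1.71 CPM, 31.1-fold, 16.0 to 69.3). They were followed by the tachykinin precursor TAC1 (272 against 29.6 CPM, 9.20-fold, 7.75 to 10.99) and PDLIM3 (246 against 26.4 CPM). PDLIM3 was among the leading genes of cluster 19, and its values within a cluster are not given. MMP9 was also higher in endothelial-like cells, at 115 against 29.4 CPM, and in cycling cells, at 218.5 against 83.15 CPM. It led the mural-like cluster 2 as well. Whether its RNA in neuron-like cells was released from other cells was not tested. Lower were the calcium-binding protein SCGN (24.9 against 408 CPM, 16.4-fold, 13.0 to 20.9), TMEM233 (11.2 against 125 CPM), RGS5 (13.8 against 136 CPM), LIX1 (28.5 against 211 CPM) and BCAM (28.2 against 206 CPM). Within cluster 20 alone, NEUROD1 was at 585 against 5.46 CPM (107-fold, 73.3 to 163), MMP9 at 67.8 against 0.405 CPM, TAC1 at 352 against 31.4 CPM, VSNL1 at 215 against 24.1 CPM and SCGN at 32.4 against 433 CPM.

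By list, proneural factors had a median log2 ratio of 0.93 in neuron-like cells (percentile 100, 5 of 11 at least 2-fold higher, HES6 at 2.04), which stayed at 0.92 without NEUROD1. It was 0.84 within cluster 19 and 0.80 within cluster 20, both without NEUROD1. The other lists are not given within a cluster, so part of their differences may come from the mixture of clusters. Interferon and antigen presentation genes stood at 1.17 (100, 5 of 9 higher), with B2M at 2.15 and HLA-B at 2.41. Immediate early genes were at 0.68 (100, 2 of 10, IER2 at 1.42), and fibrillar collagen and matrix genes at 1.07 (100, 6 of 11), where COL3A1 was at 78.7 against 25.6 CPM, beside 1736 and 2154 CPM in mesenchymal-like cells. The neuroendocrine list was at −1.01 (0.0, 3 of 5 lower), with SCGN at −3.79, CHGA at 0.15 and CHGB at 0.35. Hypoxia and glycolysis genes were at −0.38 (0.0, none of 16 at least 2-fold apart), with SLC2A1 at −0.98. The neuron list (−0.01, percentile 77.6), the synapse list (0.04, 63.9), excitability genes (−0.11, 4.63), glutamatergic genes (0.18, 86.9) and heat shock genes (0.07, 72.4) lay within the central range. Sensory genes were at −0.31 (0.13), with DRGX at −1.43. Neurotrophin receptors and ligands were at −0.35 (0.04), with NGFR at −0.76, RET at −0.85 and GFRA1 at 1.48. Cholinergic and motor genes were at 0.48 (99.5, 2 of 5 higher and 1 lower), with PHOX2A at 1.75 and ISL2 at −1.54.

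Among the transporters and enzymes of the transmitter lists, SLC17A6 was highest in neuron-like cells. SLC17A6, which loads glutamate into synaptic vesicles, was at 200 CPM (189 to 213) at 15 days and 203 CPM (187 to 219) at 45 days, with a UMI in 28.5% and 27.2% of cells thinned to 2000 UMIs, or 56.9% and 47.3% unthinned. SLC17A7 was at 83.1 and 69.9 CPM. In endothelial-like cells SLC17A6 had 1 and 0 UMIs and a thinned share of 0.0% at both times. The GABA genes were low: GAD1 at 0.190 and 2.95 CPM, GAD2 at 0 and 0.984 CPM and SLC32A1 at 0.569 and 5.58 CPM, and thinned shares were at most 0.862% (0.105 to 3.08) in neuron-like cells, or 3.40% unthinned for SLC32A1 at 45 days. Of the cholinergic genes, CHAT had 1 and 2 UMIs, while the vesicular transporter SLC18A3 was at 23.0 and 34.1 CPM. The dopamine and noradrenaline enzyme TH was at 2.09 and 3.61 CPM. Of the 12 genes of the sensory list, 9 were measured in neuron-like cells. PRPH was at 2843 and 1919 CPM, with a thinned share of 91.1% and 66.4% against 3.0% and 1.05% in endothelial-like cells (91.6% and 72.1% of neuron-like cells unthinned). ISL1 was at 325 and 242 CPM and POU4F1 at 103 and 82.0 CPM. The BDNF receptor NTRK2 was at 106 and 80.7 CPM and the NT-3 receptor NTRK3 at 9.67 and 9.51 CPM. PHOX2A, a factor of autonomic and some motor neurons, was at 12.5 and 54.1 CPM.

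**Figure D3:**
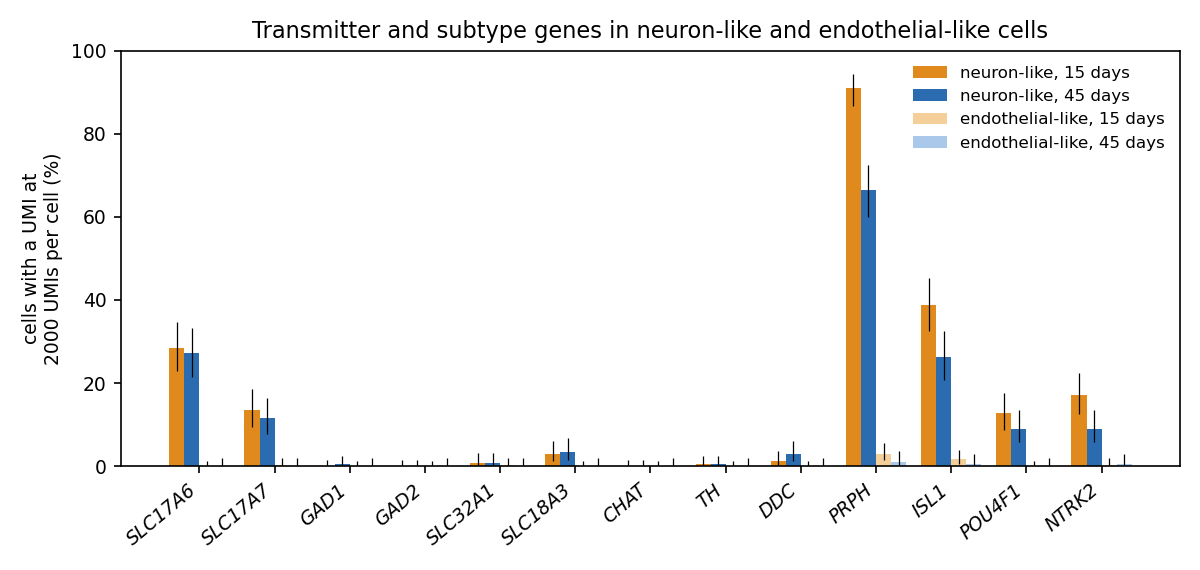
Share of cells with a UMI (%) of transmitter and subtype genes after thinning each cell to 2000 UMIs, in neuron-like and endothelial-like cells of the libraries labelled 15 and 45 days, with exact 95% binomial intervals. SLC17A6 reaches 28.5% and 27.2%, PRPH 91.1% and 66.4%, and GAD1, GAD2, SLC32A1, CHAT and TH stay at or below 0.862%.

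Endothelial-like cells of both induced libraries had more RNA of tip cell and angiogenic genes than uninduced ones. Tip cell genes, which mark the leading cells of vessel sprouts, had a median log2 ratio of 0.65 at 45 days (percentile 100, 3 of 10 at least 2-fold higher) and 0.54 at 15 days (100, 2 of 10). ESM1 (ENSG00000164283, chromosome 5, 54977864 to 55022671) was at 221 CPM without induction, 755 CPM at 15 days (3.41-fold, 3.15 to 3.71) and 871 CPM at 45 days (3.94-fold, 3.604 to 4.31). UNC5B-AS1 was at 14.0, 113 and 271 CPM (8.09-fold, 5.99 to 11.1, and 19.4-fold, 14.4 to 26.5). Its neighbour UNC5B was at 388, 704 and 828 CPM. CA2 was at 25.4, 111 and 91.9 CPM. RBP7 was 3.27-fold (2.64 to 4.07) and DGKD 3.63-fold (2.66 to 4.97) higher at 45 days. CXCL2 was 5.72-fold (3.88 to 8.66) higher at 15 days. ESM1 was among the leading genes of cluster 12, which held 273 of 507 endothelial-like cells without induction, 246 of 326 at 15 days and 164 of 220 at 45 days. Angiogenic ligands stood at 0.60 (100, 2 of 11 higher, 1 lower) and 0.35 (99.6, 1 of 9), with APLN at 1.44 and 1.01, PGF at 1.36 and 0.78, ANGPT2 at 0.67 and 0.35, and FGF2 at −1.40 at 45 days. Arterial genes were at 0.42 (99.94) and 0.26 (99.1), with GJA5 at −0.74 and −0.44. The blood-brain barrier list was at −0.56 (0.0, 3 of 10 lower) and −0.24 (0.02), with APCDD1 at −2.12 and −1.91 and CLDN5 at 0.18 and 0.19.

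The 45 day endothelial-like cells had less of APLNR, the receptor of APLN, which was at 12.5 CPM against 156 CPM without induction (12.5-fold, 7.92 to 20.9) and 163 CPM at 15 days. NTS (78.8 against 388 CPM, 4.92-fold, 4.08 to 5.98), IL33 (23.6 against 127 CPM, 5.35-fold, 3.81 to 7.74), STXBP6 (13.1 against 77.6 CPM) and ACSM3 (21.0 against 110 CPM) were lower too. Set against 15 days, MADCAM1 was at 3.28 against 95.5 CPM and NKX2-3 at 17.7 against 86.1 CPM. Cluster 25, led by NTS, APLNR, IL32, LYVE1, CAVIN2 and MADCAM1, held 120, 41 and 16 of those cells. Venous and lymphatic genes were at −0.13 (4.3) and −0.06 (11.4), with NR2F2 at −1.90 and −0.54 and LYVE1 at −0.34 and 0.62. Immediate early genes stood at −0.65 at 45 days (0.0, 4 of 14 lower, FOS at −1.88 and KLF2 at −1.78) and 0.32 at 15 days (99.8, none at least 2-fold apart), and at −1.14 between the induced libraries (0.0, 8 of 14 lower). Hypoxia and glycolysis genes were at 0.57 (100, none of 17 at least 2-fold apart), 0.05 (41.6) and, between the induced libraries, 0.62 (100). The median share of mitochondrial UMIs in these cells was 4.096% at 45 days, 5.912% at 15 days and 5.618% without induction. Targets of p53 were at 0.44 (99.97) and 0.61 (100, GDF15 at 1.53). ATF4 stress genes were at 0.42 (99.99) and 0.06 (39.4). Basement membrane genes were at 0.20 (98.2) and 0.30 (99.8), with NID2 at 1.16 and 1.15 and FN1 at −0.91 and −1.09. At 15 days LUM (4.20 against 67.9 CPM), COL1A2, COL1A1 and COL3A1 (102 against 417 CPM) were lowest, followed by ACSM3, and NEFM (59.8 against 15.6 CPM) was among the highest. COL1A1 and COL3A1 stood far higher in mesenchymal-like cells of the same libraries, and NEFM in neuron-like cells at 15 days. Counts at least 4-fold apart with 5 CPM added were 1 higher and 6 lower of 3612 genes at 45 days, and 2 and 3 of 3650 at 15 days, or 1 and 5 with median-of-ratios scaling.

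Mural-like cells of both induced libraries had less RNA of contractile and TGF-beta response genes. The contractile list had a median log2 ratio of −0.82 at 45 days and −0.92 at 15 days (both percentile 0.0, 5 of 12 at least 2-fold lower in each), with TAGLN at 158 CPM and 111 CPM against 746 CPM without induction, TPM1 at −1.36 and −1.07 and SMTN at 0.73 and 0.89. TGF-beta response genes stood at −0.94 and −0.80 (both 0.0, 5 of 10 lower in each), with CTGF at 80.8 and 48.0 against 272 CPM. PAPPA (3.17 and 1.21 against 78.0 CPM), the collagen crosslinker LOX (5.73 and 6.05 against 87.1 CPM), THBS1 (12.7 and 9.68 against 111 CPM) and, at 15 days, SFRP2 (10.9 against 142 CPM) were lower as well. Higher were the lipid carrier FABP4 (128 and 184 against 29.9 CPM), SYT1 (109 and 118 against 28.6 CPM), THBS4 at 45 days (384 against 92.9 CPM, 4.13-fold, 3.72 to 4.59), with CRABP1 and EPHB6, and PLVAP, FOXC1 and NEFM at 15 days. PLVAP stood at 77.8 against 14.1 CPM here and at 914 and 668 CPM in endothelial-like cells, and NEFM at 84.7 against 12.1 CPM here and at 10120 CPM in neuron-like cells at 15 days. Cluster 2, led by MMP9, KCNJ8 and ABCC9, held 307 of 657 mural-like cells without induction, 711 of 807 at 15 days and 866 of 1029 at 45 days. Cluster 24, led by genes that include ACTA2 and TAGLN, held 80, 48 and 65, and cluster 17, led by HES5 and ANGPT2, 270, 48 and 98. With 5 CPM added, 0 of 2911 genes were at least 4-fold higher and 7 lower at 45 days, and of 2950 genes 3 and 11 at 15 days. Without the cell filter the totals were 21 and 28.

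Mesenchymal-like cells of both induced libraries had less collagen and WNT pathway RNA and more of BMP response and hypoxia genes. Fibrillar collagen and matrix genes had a median log2 ratio of −0.70 at 45 days and −0.67 at 15 days (both percentile 0.0, 5 and 6 of 14 at least 2-fold lower, ELN the 1 higher), with COL1A1 at 535 and 504 against 2240 CPM and COL3A1 at 1736 and 2154 against 4689 CPM. COL15A1 (ENSG00000204291, chromosome 9, 98943179 to 99070792) was at 8.16 and 3.13 against 131 CPM (16.1-fold, 14.3 to 18.2, and 42.0-fold, 32.7 to 54.7), DCN at 148 and 114 against 788 CPM, DKK2 at 13.8 and 6.61 against 90.2 CPM. At 45 days the activin antagonist FST (9.39 against 60.8 CPM) was also among the lowest, and at 15 days CXCL14 (87.3 against 568 CPM) and FMOD (4.67 against 50.5 CPM). WNT pathway genes stood at −0.80 (0.0, 5 of 12 lower) and −0.90 (0.0, 6 lower, 2 higher), with SFRP1 at −1.31 and −0.49, RSPO3 at 0.76 at 45 days and DKK1 at 1.95 at 15 days. Higher were MEOX2 (170 and 165 against 27.4 CPM) and CLDN11 (116 and 115 against 17.9 CPM) at both times, LHX9 (114 against 13.1 CPM, 8.70-fold, 7.86 to 9.65), THBS4 (65.6 against 9.14 CPM) and the cartilage regulator SOX9 (62.4 against 10.4 CPM) at 45 days, and KIF5C (120 against 16.1 CPM), MGLL and SPRY4 at 15 days.

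BMP response genes were at 0.40 (percentile 99.87) and 0.54 (99.96, 1 of 9 at least 2-fold higher), with ID3 at 0.50 and 1.01. Posterior HOX genes were at 0.47 (100, 3 of 15 higher) and 0.29 (97.2), with HOXA13 at 1.12 and 0.52, HOXD13 at 1.32 at 45 days and HOXC8 at −0.94 and −0.79, and anterior HOX genes at −0.27 (0.12) and 0.37 (97.46). Hypoxia and glycolysis genes stood at 0.76 and 0.73 (both 100, 3 and 2 of 17 higher), with ENO1 at 0.79 and 0.80 and ANKRD37 at 1.32 and 1.41; without cluster 6, which these genes led, the medians were 0.30 and 0.22. Mitochondrially encoded genes were at −0.26 in both (0.145 and 0.06). Axon guidance genes were at 0.11 (30.2) and 0.48 (99.99), with SLIT2 at −1.75 and −2.03, and neurotrophin genes at −0.16 (0.515) and −0.02 (3.59), with NTF3 at −0.59 and −1.23. Nuclear respiratory chain genes (0.08, 67.5 and 0.15, 81.4), unfolded protein genes (−0.02, 9.57 and 0.11, 36.9) and Notch genes (0.09, 26.9 and 0.01, 4.83) lay within the central range. Different clusters held most of the class: 5, 1, 4 and 8 without induction (1514, 1195, 943 and 619 of 5751 cells), 0, 4, 9 and 1 at 15 days (827, 399, 312 and 312 of 2741) and 3, 0, 6 and 7 at 45 days (1399, 1208, 886 and 609 of 6154). LHX9 led cluster 3, MEOX2 and CLDN11 cluster 0, and COL15A1, DCN and FMOD cluster 15, which held 5.30%, 0.039% and 0.337% of the libraries' cells. Of 2790 genes, 5 were at least 4-fold higher and 10 lower at 45 days. Of 2855 genes, 8 and 17 were so at 15 days, or 5 and 21 with median-of-ratios scaling. None of 2829 genes was as far apart between the induced libraries.

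**Figure D4:**
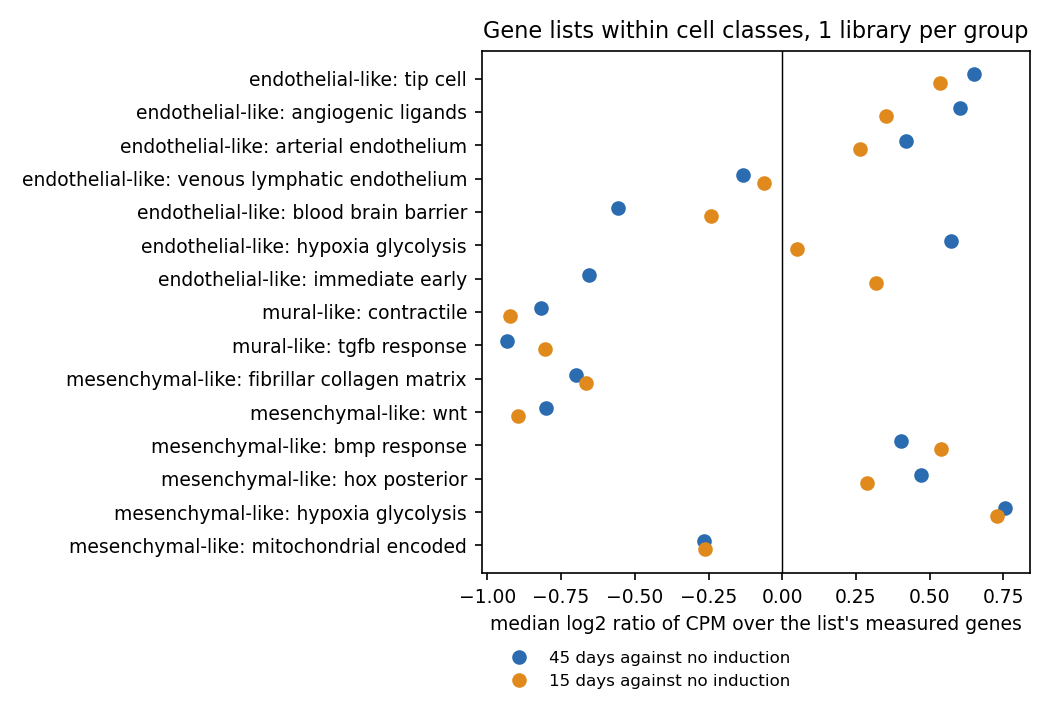
Median log2 ratio of CPM over the measured genes of lists in endothelial-like, mural-like and mesenchymal-like cells, for the 45 day and 15 day libraries against the library without induction; each point is the median of 1 list and the vertical line marks 0. Tip cell genes stand at 0.65 and 0.54, contractile genes at −0.82 and −0.92, and collagen genes at −0.70 and −0.67.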

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

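Of the tests below, the ratio of endothelial-like to mesenchymal-like cells, the hypoxia median within a band of mitochondrial share and the median under other scaling were chosen before their results were seen, and the other tests only afterwards. NEUROD1 in neuron-like cells was far higher in the 45 day library than in the library labelled 15 days. A different mixture of the neuron-like clusters is argued against, since the smaller of the fold differences within a cluster was 12.13 (8.615 to 17.629). Depth is argued against too, since 51.429% (41.474 to 61.301) of cluster 20 cells thinned to 2000 UMIs had a NEUROD1 UMI at 45 days and 2.273% (0.623 to 5.717) at 15 days. An end of doxycycline before harvest in the 15 day library may account for it and stays open: 58.863% of its neuron-like cells were in cluster 20, against 35.714% at 45 days, but the labels do not say which 15 days were induced. A cassette transcript counted outside the annotated gene was not tested.

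The share of endothelial-like cells was lower at 45 days than in both other libraries. Cells hidden by the filter or by the names are argued against, since the endothelial list had a median log2 ratio of −0.958 (−1.232 to −0.646, 15 genes) over all barcodes against no induction. Dilution by neuron-like cells alone is argued against, since the ratio of endothelial-like to mesenchymal-like cells was 0.4055 times the uninduced ratio (0.3446 to 0.476). Organoid to organoid variation, or uneven recovery on dissociation, could give the same difference and cannot be told apart from the duration of induction with 1 library per group.

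Hypoxia and glycolysis genes were higher in mesenchymal-like cells of both induced libraries, which also had fewer mitochondrial UMIs (medians of 2.643% at 45 days and 3.233% at 15 days, against 4.209%). Among mesenchymal-like cells with 3 to 6% mitochondrial UMIs (2081 at 45 days, 1030 at 15 days, 2123 uninduced) the median log2 ratio was 0.431 at 45 days and 0.448 at 15 days (percentiles 99.97 and 99.96). The hypoxia-led cluster 6 had a median of 0.699% mitochondrial UMIs and held 79 cells without induction, 291 at 15 days and 886 at 45 days. Without cluster 6 the list medians were 0.30 at 45 days and 0.22 at 15 days. Cells with few mitochondrial UMIs may therefore hold part of the difference, and how much stays open. Scaling is argued against, since with median of ratios the medians were 0.643 and 0.588 (both percentile 100). The size of the organoids, or the handling of a library, cannot be told apart from induction with 1 library per group.

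Cells of cluster 21, led by the liver secretory genes ALB, AFP and APOA1, stood outside the named classes and made up 3.86% (3.347 to 4.427) of the library labelled 15 days, against 0.061% without induction and 0.011% at 45 days. Anterior HOX genes at 45 days against no induction had a median log2 ratio of 0.596 in endothelial-like cells and −0.67 in cycling cells, opposite directions whose difference was not tested. Cycling genes at 45 against 15 days stood at 0.565 in neuron-like and −0.658 in endothelial-like cells, a difference that was not tested. Tip cell genes in the same comparison stood at 0.581 in neuron-like and −0.559 in cycling cells, a difference that was not tested. Immediate early genes there stood at 0.682 in neuron-like and −1.143 in endothelial-like cells, a difference that was not tested.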

How the results depend on the processing

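The tests that leave out neuron-like cells, cluster 6, 15 or 21, that count neuron-like cells by markers, or that name clusters on 3 markers, were chosen after the results were seen. No paired analysis was possible because there was 1 library per group. Of the medians of lists that answer a comparison, 320 values under an alternative counted as kept, 10 as moved and 4 as reversed. Of the other list medians, 654 counted as kept, 11 as moved and 4 as reversed. These counts do not give the number of sign changes. The hypoxia and glycolysis median over all cells at 45 against 15 days, −0.059, changed sign and counted as moved. It was 0.153 with the mean of each cell's own CPM and 0.13 without cluster 21. Of the log2 ratios of named genes 1831 kept their size and 249 moved. The endothelial-like share stayed lowest at 45 days in the 8 alternatives that gave shares (2.11% to 2.98%, against 4.95% to 7.16% without induction and 5.28% to 7.91% at 15 days). The neuron-like share stayed higher at 15 days (3.40% to 5.95%) than at 45 days (1.12% to 3.59%) in each of 10. Depth limits what is seen: a gene with no UMI in a whole library is bounded only at 0.0585, 0.0661 and 0.0541 CPM (none, 15 and 45 days). Below, by setting, are shares of neuron-like, endothelial-like, mural-like and mesenchymal-like cells, and of cells with a NEUROD1 UMI, beyond their counting interval. Counts that moved by over 1.5 times and list medians that reversed are given too, and, for lists that answer a comparison, medians that left their interval. Not listed are 71 values of other shares and 11 of other list medians that moved. The cycling share ran from 8.48% to 10.9% without induction. The haematopoietic-like share ran from 0.656% to 1.46% without induction and from 1.01% to 2.13% at 15 days. The cause was not tested except where a floor or a left-out cluster sets which genes or cells enter.

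Without a cell filter, the shares were 3.40% at 15 days and 1.12% at 45 days (neuron-like cells), and 7.16% without induction, 7.91% at 15 days and 2.90% at 45 days (endothelial-like cells), and 3.61% without induction, 6.66% at 15 days and 5.58% at 45 days (mural-like cells), and 56.5% at 15 days (mesenchymal-like cells). The genes at least 4-fold apart numbered 21 in mural-like cells, 65 in cycling cells and 26 in haematopoietic-like cells (45 days against none), and 28 in mural-like cells and 62 in cycling cells (15 days against none). The median log2 ratio was −0.072 for endothelial genes in all cells at 15 days against none. With a mitochondrial limit of 10%, the shares were 5.47% without induction, 5.28% at 15 days and 2.11% at 45 days (endothelial-like cells), and 3.04% without induction, 7.55% at 15 days and 7.07% at 45 days (mural-like cells), and 76.7% without induction, 64.6% at 15 days and 74.2% at 45 days (mesenchymal-like cells). The genes at least 4-fold apart numbered 11 in endothelial-like cells (15 days against none), and 14 in mural-like cells and 28 in haematopoietic-like cells (45 days against none). The median log2 ratio was −0.003 for endothelial genes in all cells at 15 days against none and 0.033 for epithelial genes in all cells at 15 days against none. Without removal of doublets, the shares were 7.02% without induction and 2.98% at 45 days (endothelial-like cells), and 4.12% without induction, 11.3% at 15 days and 8.80% at 45 days (mural-like cells), and 72.1% without induction and 57.3% at 15 days (mesenchymal-like cells). The genes at least 4-fold apart numbered 9 in endothelial-like cells, 22 in mural-like cells and 21 in haematopoietic-like cells (15 days against none), and 2 in endothelial-like cells and 6 in haematopoietic-like cells (45 against 15 days), and 17 in mural-like cells (45 days against none).

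At Leiden resolution 0.5, the shares were 5.24% without induction (endothelial-like cells). The genes at least 4-fold apart numbered 3 in endothelial-like cells (15 days against none). At Leiden resolution 2.0, the shares were 5.22% without induction (endothelial-like cells), and 7.19% without induction, 8.82% at 15 days and 8.64% at 45 days (mural-like cells), and 71.4% without induction, 61.2% at 15 days and 72.3% at 45 days (mesenchymal-like cells). The genes at least 4-fold apart numbered 3 in endothelial-like cells and 16 in haematopoietic-like cells (15 days against none). With markers and list genes left out of the variable genes, the shares were 5.61% without induction (endothelial-like cells), and 3.39% without induction, 6.34% at 15 days and 5.42% at 45 days (mural-like cells), and 74.1% without induction, 63.5% at 15 days and 74.7% at 45 days (mesenchymal-like cells). With each library clustered alone, the shares were 5.36% at 15 days (endothelial-like cells), and 6.95% without induction, 12.9% at 15 days and 7.91% at 45 days (mural-like cells), and 71.1% without induction, 57.1% at 15 days and 73.5% at 45 days (mesenchymal-like cells). With cells thinned before clustering, the shares were 4.88% at 15 days and 2.70% at 45 days (neuron-like cells), and 4.95% without induction and 2.11% at 45 days (endothelial-like cells), and 3.68% without induction, 5.82% at 15 days and 4.91% at 45 days (mural-like cells), and 75.3% without induction, 65.6% at 15 days and 76.0% at 45 days (mesenchymal-like cells).

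With median-of-ratios scaling, the median log2 ratio was −0.12 for endothelial genes in all cells at 15 days against none. With a pseudocount of 1 CPM, the genes at least 4-fold apart numbered 9 in endothelial-like cells (15 days against none), and 7 in endothelial-like cells and 1 in mural-like cells (45 against 15 days), and 12 in mural-like cells (45 days against none). The median log2 ratio was −1.16 for endothelial genes in all cells at 45 against 15 days and 0.80 for hypoxia and glycolysis genes in mesenchymal-like cells at 15 days against none. With a pseudocount of 10 CPM, the genes at least 4-fold apart numbered 4 in endothelial-like cells and 9 in cycling cells (45 days against none), and 14 in mesenchymal-like cells and 9 in cycling cells (15 days against none). With a floor of 20 CPM, the genes at least 4-fold apart numbered 44 in all cells, 16 in endothelial-like cells, 13 in mural-like cells, 24 in mesenchymal-like cells and 40 in haematopoietic-like cells (45 days against none), and 115 in all cells, 15 in endothelial-like cells, 24 in mural-like cells, 39 in mesenchymal-like cells, 28 in cycling cells and 76 in haematopoietic-like cells (15 days against none), and 29 in all cells, 12 in endothelial-like cells, 4 in mural-like cells, 6 in mesenchymal-like cells and 36 in haematopoietic-like cells (45 against 15 days). With a floor of 100 CPM, the genes at least 4-fold apart numbered 11 in all cells and 7 in cycling cells (45 days against none), and 35 in all cells, 2 in endothelial-like cells, 7 in mural-like cells, 13 in mesenchymal-like cells, 9 in cycling cells and 15 in haematopoietic-like cells (15 days against none), and 10 in all cells, 14 in neuron-like cells, 1 in endothelial-like cells and 3 in haematopoietic-like cells (45 against 15 days). With the mean of each cell's own CPM, the genes at least 4-fold apart numbered 16 in all cells (45 days against none), and 35 in all cells (15 days against none). The median log2 ratio was 0.30 for endothelial genes in all cells at 15 days against none, 0.050 for chondrogenic genes in all cells at 15 days against none, 0.14 for epithelial genes in all cells at 15 days against none and 0.15 for hypoxia and glycolysis genes in all cells at 45 against 15 days. Without thinning, the shares were 0.630% at 15 days and 3.67% at 45 days (cells with a NEUROD1 UMI). With thinning to 1000 UMIs, the shares were 0.0% without induction, 0.118% at 15 days and 1.72% at 45 days (cells with a NEUROD1 UMI).

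Chosen after seeing the data were the tests that follow. With each library clustered alone and 3 markers enough, the shares were 5.35% without induction (neuron-like cells). Counted by 5 of 15 markers, the shares were 4.88% at 15 days and 2.26% at 45 days (neuron-like cells). Without cluster 21, the genes at least 4-fold apart numbered 3 in all cells (45 against 15 days). The median log2 ratio was 0.13 for hypoxia and glycolysis genes in all cells at 45 against 15 days. Without cluster 15, the median log2 ratio was −0.11 for endothelial genes in all cells at 15 days against none. Without neuron-like cells, the genes at least 4-fold apart numbered 16 in all cells (45 days against none), and 29 in all cells (15 days against none). The median log2 ratio was 0.69 for neuron genes in all cells at 45 days against none, 0.88 for neuron genes in all cells at 15 days against none, 0.009 for chondrogenic genes in all cells at 15 days against none and −0.22 for neuron genes in all cells at 45 against 15 days. Without cluster 6, the median log2 ratio was 0.30 for hypoxia and glycolysis genes in mesenchymal-like cells at 45 days against none and 0.22 for hypoxia and glycolysis genes in mesenchymal-like cells at 15 days against none.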

Other observations

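No hypothesis was tested for the values in this part. Haematopoietic-like cells, led by the complement genes C1QA and C1QB, had more interferon RNA in both induced libraries. The interferon and antigen presentation list had a median log2 ratio of 1.44 at 45 days (percentile 100, 9 of 13 genes at least 2-fold higher) and 1.54 at 15 days (100, 10 of 13), from 74 and 84 cells against 72 uninduced cells. Cluster 22 held 54 of them without induction, 81 at 15 days and 64 at 45 days, and cluster 27 held 18, 3 and 10. IFIT1, an interferon-induced RNA-binding protein, was at 199 against 12.04 CPM at 15 days (16.5-fold, 6.91 to 51.7), and IFIT3 at 130 against 9.63 CPM (13.5-fold, 5.08 to 50.5). RSAD2 was at 63.4 against 2.41 CPM (26.3-fold, 4.48 to 1064), and the chemokine CCL8 at 108 against 0 CPM, at least 14.89-fold higher. DNASE1L3 was higher in both, at 129 CPM (53.4-fold, 9.25 to 2143) and 79.6 CPM (33.1-fold, 5.69 to 1329) against 2.41 CPM. CXCL14 (2.95 against 508 CPM) and the mesenchymal markers LUM (8.85 against 200 CPM) and TWIST1 (16.2 against 202 CPM) were lower in the same cells at 15 days. The mesenchymal list was at −2.43 there (0.0, 11 of 12 lower). At 45 days CXCL14 was at 54.3 CPM and TWIST1 at 38.2 CPM, and the list at −1.27 (0.0, 7 of 12 lower). Whether this RNA was released from other cells was not tested. Among cycling cells at 45 days LHX9 was at 193 against 18.4 CPM (10.5-fold, 8.61 to 13.0) and SOX9 at 60.6 against 7.76 CPM. Cluster 13 held 359 of the 698 cycling cells without induction, 63 of 332 at 15 days and 239 of 602 at 45 days, and cluster 16 held 127, 191 and 138. Of 2996 genes there, 7 were at least 4-fold higher and 9 lower, or 5 and 11 with median-of-ratios scaling; at 15 days 7 were higher and 10 lower, or 5 and 13. Without the cell filter 7 were higher and 58 lower at 45 days, and 14 and 48 at 15 days.

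The epithelial-like clusters 10 and 18, and cluster 26, which has no class name, differed between libraries in their genes as well as in their shares. Cluster 10, with the basal keratinocyte genes KRT15, KRT5 and TP63, had 27 genes at least 4-fold higher and 8 lower of 3117 at 45 days, and 50 and 11 of 3213 at 15 days, against no induction. The WNT inhibitor WIF1 was at 245 against 16.0 CPM at 45 days (15.3-fold, 9.93 to 24.9), COL14A1 at 189 against 13.7 CPM and S100A9 at 4.09 against 58.0 CPM. At 15 days the suprabasal keratin KRT13 was at 814 against 38.9 CPM (20.9-fold, 15.8 to 28.2), TNFSF10 at 346 against 8.39 CPM (41.2-fold, 22.9 to 83.0), AMTN at 180 against 0 CPM, at least 78.54-fold higher, and TFAP2B at 3.13 against 175 CPM (55.8-fold, 23.6 to 173). Hypoxia and glycolysis genes in cluster 10 had a median of 1.43 at 45 days (100, 13 of 17 higher) and 0.95 at 15 days (100, 8 of 17 higher). The median share of mitochondrial UMIs in its cells was 1.793% at 45 days, 4.294% at 15 days and 6.535% without induction, with 34.71%, 11.79% and 12.32% of cells under 1%. In cluster 18, 74 cells at 45 days against 261 uninduced cells with medians of 4.258% and 7.28% mitochondrial UMIs, KRT1 was at 549 against 8.13 CPM (67.5-fold, 45.8 to 104), SPRR2F at 958 against 28.6 CPM and KRT4 at 807 against 73.4 CPM, while SLN was at 0 against 244 CPM, at least 64.4-fold lower. In cluster 26, 53 cells at 15 days against 76 uninduced cells with medians of 0.282% and 3.171% mitochondrial UMIs, INS, which encodes insulin, was at 201 against 0 CPM, at least 41.9-fold higher, and POU5F1, a pluripotency factor, at 103 against 0 CPM, at least 21.4-fold higher. The gut hormone gene MLN was at 3.07 against 1495 CPM there (487-fold lower, 135 to 4031). How many cells carried the UMIs of these genes is not given, and 1 uninduced cell of cluster 26 held 74 NEUROD1 UMIs.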
